A study of Monomorium pharaonis with 32 samples.

How the data were processed

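Brains of adult pharaoh ants were dissected on ice from animals fed on mealworms, per the labels' protocols, and used for RNA-seq and for ATAC-seq, which reads where the transposase Tn5 can cut chromatin. Each assay covered 4 castes (gyne, male, queen and worker) with 4 biological replicates per caste, per the series' design text, so there were 16 libraries per assay. The sources used here do not say how many brains entered a library.

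The RNA values are raw read counts per gene in one deposited table. RNA was polyadenylated and libraries were made with an adapted Smart-seq2 method, a full-length cDNA protocol, per the labels' protocols. The ATAC values are raw read counts per peak in a second deposited table, over one peak set shared by all 16 libraries, made with an in-house Tn5, per the labels' protocols. HISAT2, Bowtie2, featureCounts, bedtools and DESeq2 are named, without version or role, per the submitters' processing notes. The peak caller, its threshold, the treatment of duplicate reads, the Tn5 offset and the use of strand in counting are not given in the sources used here. Coordinates are on assembly ASM326058v2 and were taken, with gene names, from the deposited annotation, NCBI release 101 per the file headers. All 14131 genes of the count table were found in it. Peak starts were taken as counted from 0, since 341 peaks start at 0, and are printed counted from 1.

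Counts in genes ranged from 23311783 to 40265210 per RNA library, and counts in peaks from 6515651 to 94199937 per ATAC library. The biological coefficient of variation was 4.83% for RNA and 16.6% for ATAC. Male ATAC libraries were the shallowest as a caste. Smart-seq2 reads carry no molecular identifiers, and counts of both assays can include PCR copies. No pair of replicates within a caste agreed within sampling noise (chi-square per degree of freedom 2.19 or more for RNA and 2.86 or more for ATAC), so all were kept as separate replicates.

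Genes and peaks were filtered with edgeR's filterByExpr by caste, which left 12375 genes and 38943 of 38946 peaks. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test in one fit per assay over 16 libraries with caste as the only factor. P-values were two-sided and adjusted by Benjamini-Hochberg, and a gene or peak was called at an adjusted p below 0.05. The 4 main comparisons were gyne against worker, queen against gyne, queen against worker and male against gyne, and male against queen and male against worker were secondary. The SE of a log2 fold change is its size divided by the square root of F. CPM use the TMM-scaled library size. A peak within 1 kb of an annotated transcript start was assigned to a promoter, and others to exon, intron or intergenic sequence.

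Gene lists were built from product names in the annotation by patterns fixed before the data were examined, as were the groups, tests, alternative settings and the rule for named genes. The 30 lists were tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists of a comparison. They covered markers of tissues a dissected brain could carry (photoreceptor and phototransduction, muscle, fat body and yolk, cuticle and epidermis, hemocyte, gut and salivary gland), brain cell types (glia, mushroom body), and signalling, hormone, chemosensory, metabolic and housekeeping groups. Lists rest on names inferred by homology, and members matched by wording only were found afterwards: 2 pyruvate dehydrogenase regulators in the fat body list and 1 twitching mobility protein in the muscle list. The gut list includes antichymotrypsin-2, an inhibitor, and the transmitter receptor list GABA transporter 1.

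Named genes were, per main comparison, the 5 largest rises and 5 largest falls among called genes with no overlap of the libraries of the 2 castes, at least 10 CPM in the higher caste and a product name other than uncharacterized, the called gene of smallest adjusted p of up to 14 lists, and a set of genes known from caste work, called or not. Lists are described with up to 4 called members of smallest adjusted p. For secondary comparisons the 2 largest changes each way are named. Named peaks were the 3 largest changes each way within 1 kb of a start, without overlap of libraries, and up to 3 called peaks of smallest adjusted p at named genes.

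Spearman's rho between RNA and promoter fold changes across genes was set against all 35 splits of the 8 ATAC libraries of a pair into 4 and 4. Counts of calls were set against the same kind of splits, or against drawn groupings for the 4-caste test and for calls shared by 2 comparisons. The edgeR, voom, DESeq2 and camera steps were tested on simulated data. With 50 genes planted at each size between gyne and worker among 12329 genes, edgeR recovered 56%, 82%, 94% and 100% at 1.2-, 1.5-, 2- and 4-fold, with 6 false calls of 172. Among 38943 peaks the shares were 0%, 24%, 88% and 100%, with 7 false calls of 113.

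Alternatives set beforehand were DESeq2 1.42.0, its size factors in edgeR, total counts in place of TMM and voom with quantile normalization for ATAC, no filter on low counts, voom with sample quality weights, only the 2 castes compared, a 2-fold minimum, the replicate number as a block, and leaving out each replicate. Alternatives added after the data were seen were ATAC libraries thinned to the total of the shallowest, the share of counts in the strongest decile of peaks as a covariate, ATAC without worker libraries 1 and 4, and lists without the 3 members matched by wording only. A decile of the peaks (3894) was ranked by mean CPM over all ATAC libraries. Genes without a product name were tested but not named, and no reference genome sequence was used here.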

Results

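The series holds RNA and open-chromatin profiles of dissected adult brains of the pharaoh ant, Monomorium pharaonis, a small tropical ant whose colonies keep many egg-laying queens. Each of the 4 adult castes was sampled: gynes (virgin winged females that can become queens), queens (reproductive females), workers (wingless females that do not reproduce in this species) and males. Per the labels, each caste has 4 biological replicates for RNA-seq and 4 for ATAC-seq, a method in which the transposase Tn5 cuts accessible DNA, 32 libraries in all. The RNA libraries held 23311783 to 40265210 counts in gynes, 28994627 to 36719561 in males, 24237960 to 39072439 in queens and 32482609 to 35665743 in workers. ATAC depth differed between castes: 51018215 to 94199937 counts in peaks in gynes, 12748094 to 44528539 in queens, 6515651 to 65765582 in workers and 7865588 to 10306212 in males. CPM, counts relative to TMM-scaled library size, are given as mean ± SD over n = 4 libraries, and log2 fold changes as value ± SE, n = 4 per caste. Genes and peaks said to be higher, lower, to rise or to fall passed edgeR at an adjusted p below 0.05.

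Of 12375 genes tested, 10533 (85.1%) differed among the 4 castes, and so did 23559 of 38943 ATAC peaks (60.5%). RNA libraries of one caste correlated at 0.995 to 0.997 across genes, and libraries of different castes at 0.965 to 0.992. The first principal component of the RNA values (55.8% of the variance) parted males from females, the second (16.9%) parted workers from queens, and the third (9.12%) parted gynes from queens. ATAC libraries of one caste correlated at 0.941 to 0.994 across peaks, below the RNA values. Most RNA differences were small: 82.0% of the genes called between gynes and workers, 81.9% between queens and gynes, 79.1% between queens and workers and 66.3% between males and gynes differed by less than 1.5-fold.

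**Figure D1:**
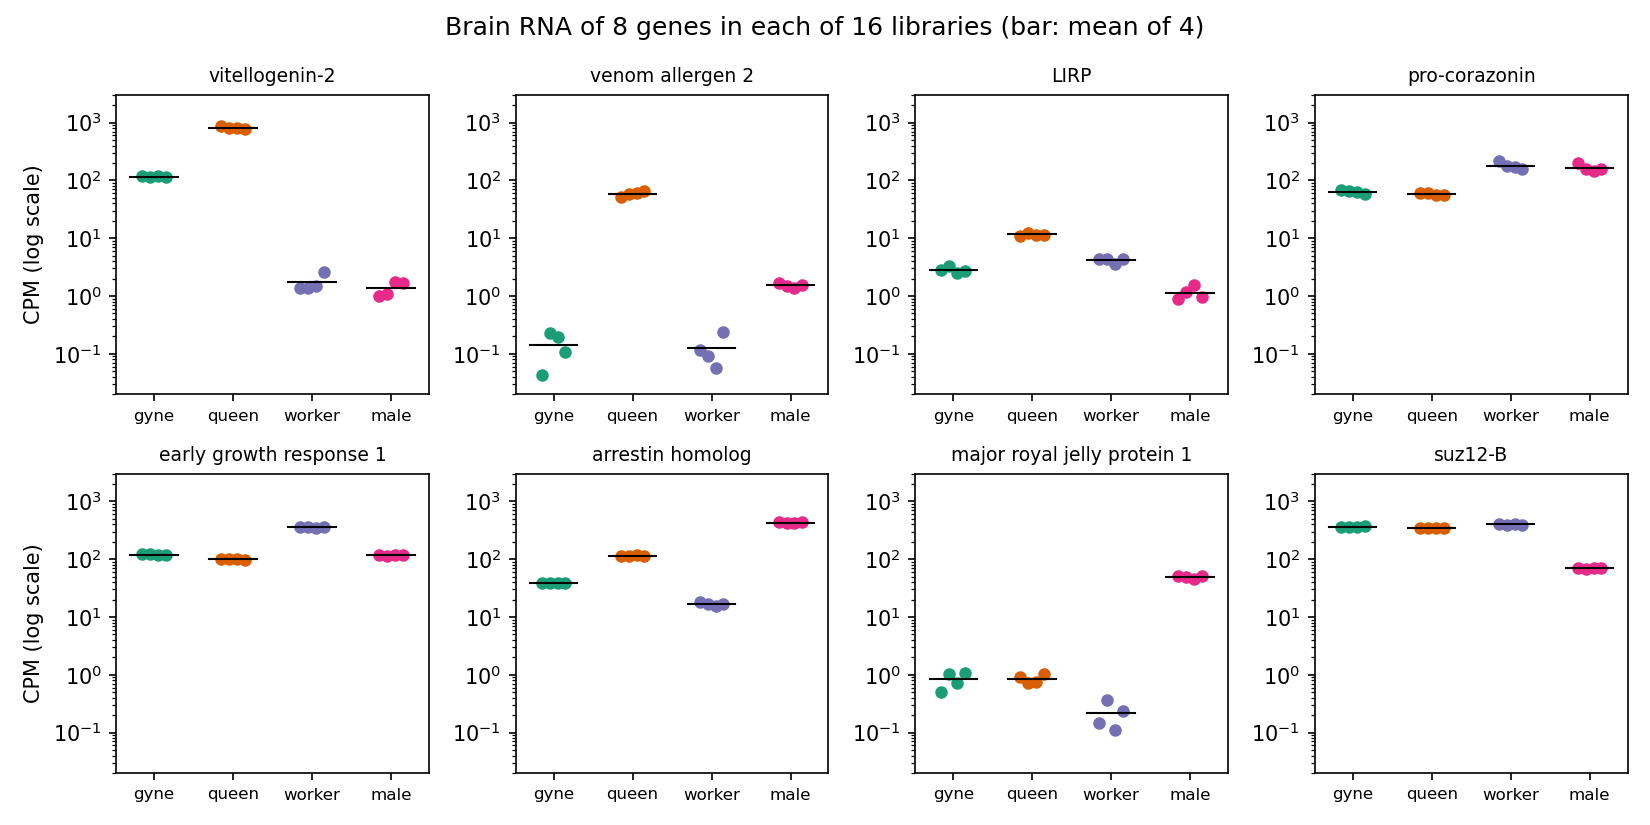
Brain RNA of 8 genes. The vertical axis gives CPM on a log scale, each point is 1 of the 16 libraries and each bar the mean of 4. Vitellogenin-2 averaged 818 CPM in queens and 117 in gynes, the arrestin homolog 429 CPM in males, and suz12-B 69.0 CPM in males against 359.8 in gynes.

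Gyne brains were compared with worker brains, the contrast between the winged and the wingless female caste. Vitellogenin-2 (LOC105835926, scaffold NW_021014891.1, positions 4002 to 10915, minus strand), a yolk protein precursor, had 117 ± 1.59 CPM in gynes and 1.72 ± 0.578 in workers (log2 fold change 6.08 ± 0.100, adjusted p = 3.27e-20). Hypertrehalosaemic prohormone (LOC105837209, 2.62 ± 0.0638), precursor of a peptide that raises blood sugar in insects, was 6.14-fold higher in gynes. Workers had 9.54-fold more maltase 1 RNA (LOC105832682, 97.1 ± 2.30 against 10.2 ± 0.409 CPM, -3.25 ± 0.0519, adjusted p = 3.27e-20) and 6.92-fold more alpha-amylase 2 (LOC105839346, -2.79 ± 0.113). Early growth response protein 1 (LOC105838685), an immediate early transcription factor, stood at 354 ± 6.36 CPM in workers and 119 ± 1.60 in gynes (-1.57 ± 0.0283, adjusted p = 9.85e-20), and nuclear receptor subfamily 4 group A member 2 (LOC105838030), of the same kind, differed by -2.04 ± 0.0466.

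Also among the largest rises in gynes were cysteine sulfinic acid decarboxylase, an enzyme of taurine synthesis (LOC105836112, 2.25 ± 0.0895), glycine receptor subunit alpha-3, a ligand-gated chloride channel (LOC105840455, 2.14 ± 0.0483), and retinal homeobox protein Rx1, a transcription factor of eye and forebrain development (LOC105838472, 1.86 ± 0.0752). Other large falls were in collagen alpha-1(II) chain, an extracellular matrix protein (LOC105833881, -3.66 ± 0.0767), glycine-rich cell wall structural protein 1.8 (LOC105834130, -2.89 ± 0.0833) and ras-related and estrogen-regulated growth inhibitor, a small GTPase (LOC105835388, -2.55 ± 0.0719). The adjusted p of these 6 genes was at most 5.79e-14. Single members of other lists also differed: putative odorant-binding protein A10 (LOC105834049, -2.20 ± 0.0731), neuropeptide SIFamide receptor (LOC105832930, 0.99 ± 0.0397), voltage-dependent calcium channel type A (LOC105833674, -0.77 ± 0.0355), synaptotagmin-10-like, a vesicle protein (LOC105831027, -0.65 ± 0.0300), and ecdysone 20-monooxygenase, which makes the active moulting hormone (LOC105834373, 1.21 ± 0.0642). In all, 3052 genes were higher in gynes and 2913 lower, of which 117 and 192 differed by 2-fold or more.

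Of 30 gene lists fixed before the data were examined, 6 passed the set test between gynes and workers. Mushroom body genes, named after the learning and memory centre of the insect brain, fell in gynes: of 19 measured, 2 were higher and 17 lower, with the same counts adjusted over the list alone (camera adjusted p = 7.07e-08, adjusted p = 0.183 with an estimated correlation). Among them were protein kinase C, brain isozyme (LOC105833362, -0.74 ± 0.0357), inositol 1,4,5-trisphosphate receptor, a calcium release channel (LOC105835203, -0.55 ± 0.0291), and mushroom body large-type Kenyon cell-specific protein 1 (LOC105832848, -0.77 ± 0.0510). Neuropeptides and peptide hormones fell: of 26 measured, 2 were higher, 18 lower and 6 did not pass, the same adjusted over the list alone. The set test's adjusted p was 2.39e-05 (adjusted p = 0.183 with an estimated correlation). Pro-corazonin, precursor of a neuropeptide related to adipokinetic hormone (LOC105830031, -1.50 ± 0.0875), tachykinins (LOC105833215, -0.74 ± 0.0415) and diuretic hormone 44 (LOC105836878, -0.40 ± 0.0303) were lower in gynes. Biogenic amine genes fell: of 29 measured, 4 were higher, 13 lower and 12 did not pass, the same adjusted over the list alone. Their camera adjusted p was 0.0160 (adjusted p = 0.202 with an estimated correlation). The lower ones included tyramine receptor 2 (LOC105828639, -0.75 ± 0.0305), dopamine receptor 2 (LOC105832565, -0.72 ± 0.0461) and tyrosine decarboxylase, which makes tyramine (LOC105835873, -0.42 ± 0.0384). Cytosolic ribosomal proteins rose: of 79 measured, 41 were higher, 0 lower and 38 did not pass, with 44 higher and 0 lower adjusted over the list alone. In camera the list had an adjusted p of 9.35e-06 (adjusted p = 0.717 with an estimated correlation). Cell cycle and DNA replication genes rose: of 33 measured, 13 were higher, 1 lower and 19 did not pass, the same adjusted over the list alone. Tested with camera, they had an adjusted p of 0.0156 (adjusted p = 0.202 with an estimated correlation). DNA polymerase epsilon subunit 4 (LOC105831543) changed by 1.55 ± 0.115 and Mcm6, part of the replication helicase (LOC105836617), by 0.39 ± 0.0427.

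Markers of other tissues moved between the same libraries. Muscle genes fell: of 37 measured, 4 were higher, 18 lower and 15 did not pass, with 4 higher and 19 lower adjusted over the list alone. Camera gave them an adjusted p of 0.00200 (adjusted p = 0.183 with an estimated correlation). They included titin (LOC105837510, -1.12 ± 0.0464) and myosin regulatory light chain 2 (LOC105835488, 1.59 ± 0.310 against 5.66 ± 0.384 CPM, -1.80 ± 0.109). Photoreceptor genes did not pass as a list (7 higher, 5 lower of 21, adjusted p = 0.586), but the arrestin homolog, which ends signalling in photoreceptors (LOC105833829, 1.21 ± 0.0400), was higher in gynes. The set test made no call for the lists of fat body and yolk (5 higher, 5 lower of 20), cuticle and epidermis (10 higher, 4 lower of 37), hemocyte (3 higher, 6 lower of 11), gut and salivary gland (9 higher, 9 lower of 36) or glia (3 higher, 2 lower of 10). The other 24 lists did not pass (adjusted p from 0.0582 to 0.950), and the median, mean and test differed in sign for cytochrome P450 and detoxification, fat body and yolk, fatty acid and hydrocarbon synthesis, glia, gut and salivary gland, heat shock and chaperones, insulin and TOR and photoreceptor and phototransduction. All 6 calls of lists were lost with an estimated correlation.

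**Figure D2:**
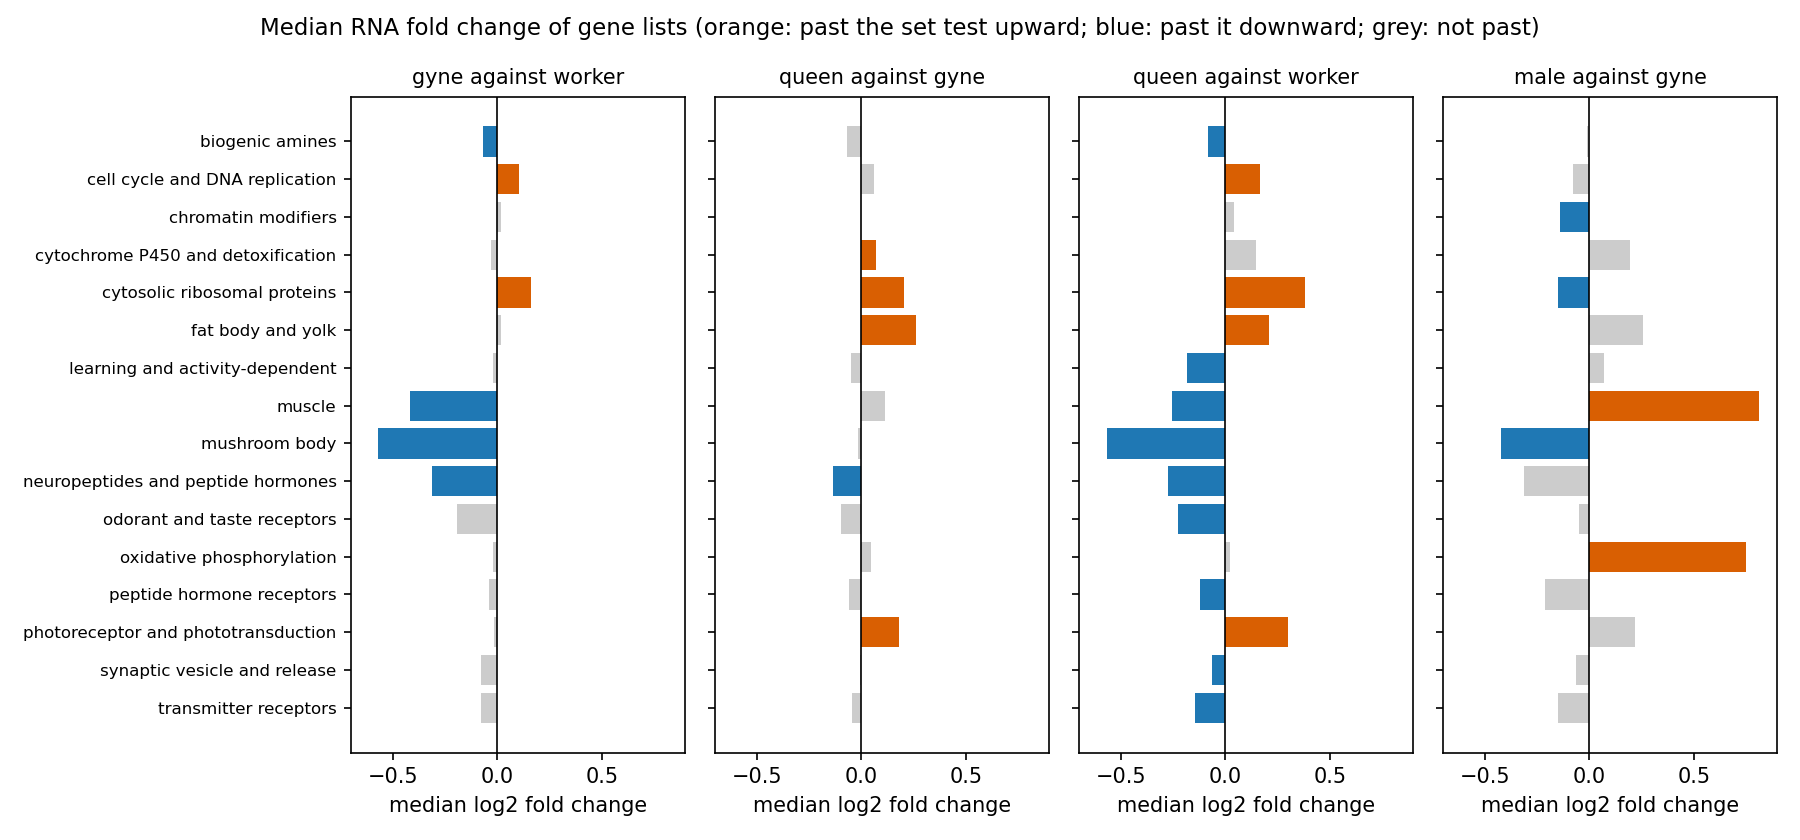
Median log2 fold change of the members of 16 gene lists (horizontal axis) in the 4 main comparisons (panels). Orange and blue bars passed the set test upward and downward with a preset correlation, and grey bars did not. The mushroom body list had a median of -0.57 in gyne against worker and -0.42 in male against gyne, and oxidative phosphorylation 0.75 in male against gyne.

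Accessibility also differed between gynes and workers: 4868 peaks were higher in gynes and 4721 lower. 10.9% of the higher peaks but 38.6% of the lower ones lay within 1 kb of an annotated transcript start, against 23.9% of all peaks tested, while introns held 46.6% and 20.7%. Without matching peaks by height, this promoter difference rested on worker libraries 1 and 4. Over all peaks it missed the threshold (-0.237, log2, promoter minus other peaks, exact permutation p = 0.286, n = 4 per caste). Without these 2 libraries it turned, to 0.0452 and to promoter shares of 21.6% of the higher and 15.1% of the lower peaks. At matched height worker libraries 2 and 3 (0.0555 and -0.0178) still lay above all gyne libraries (-0.165 to -0.0361). The promoter peak with the largest rise in gynes lay 156 bp from a start of neprilysin-1, a peptide-degrading protease (LOC105832379, NW_021020864.1, positions 10414826 to 10415234), with 8.73 ± 1.22 CPM in gynes and 1.33 ± 0.526 in workers (2.53 ± 0.241, adjusted p = 1.98e-07), and the RNA of this gene differed by 2.24. Peaks at band 4.1-like protein 4 (LOC105831386, NW_021015444.1, positions 209351 to 210000, 1.88 ± 0.285) and cyclin-dependent kinase 4 (LOC105838129, NW_021016313.1, positions 16288224 to 16288584, 1.81 ± 0.248) rose while their RNA did not pass. The largest falls were at homeotic protein Sex combs reduced (LOC105830120, -1.84 ± 0.308), THAP domain-containing protein 1 (LOC105834939, -1.73 ± 0.315) and C2H2 finger domain transcription factor crzA (LOC105829019, -1.72 ± 0.242), of which only the last differed in RNA (-0.81). At genes named for their RNA, 6 peaks within 1 kb of a start were called at genes called in RNA, 5 of them in the same direction, including Rx1 (NW_021019842.1, positions 7467 to 8210, 1.29 ± 0.192) and glycine receptor alpha-3 (NW_021016313.1, positions 2165204 to 2165792, 1.06 ± 0.170). Worker libraries 1 and 4 held 57.5% and 57.2% of their counts in the strongest decile of peaks, against 53.1% and 51.0% in libraries 2 and 3. Limma voom with sample quality weights called 10184 higher and 11807 lower peaks. Its weights were 7.51 for worker 2 and 0.241 to 0.516 for workers 1, 3 and 4. Voom with quantile normalization gave 8054 and 8507, and edgeR without gyne replicate 3 called 2705 lower. Without worker libraries 1 and 4, an alternative added after the data were seen, 4216 higher and 3223 lower peaks were called.

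**Figure D3:**
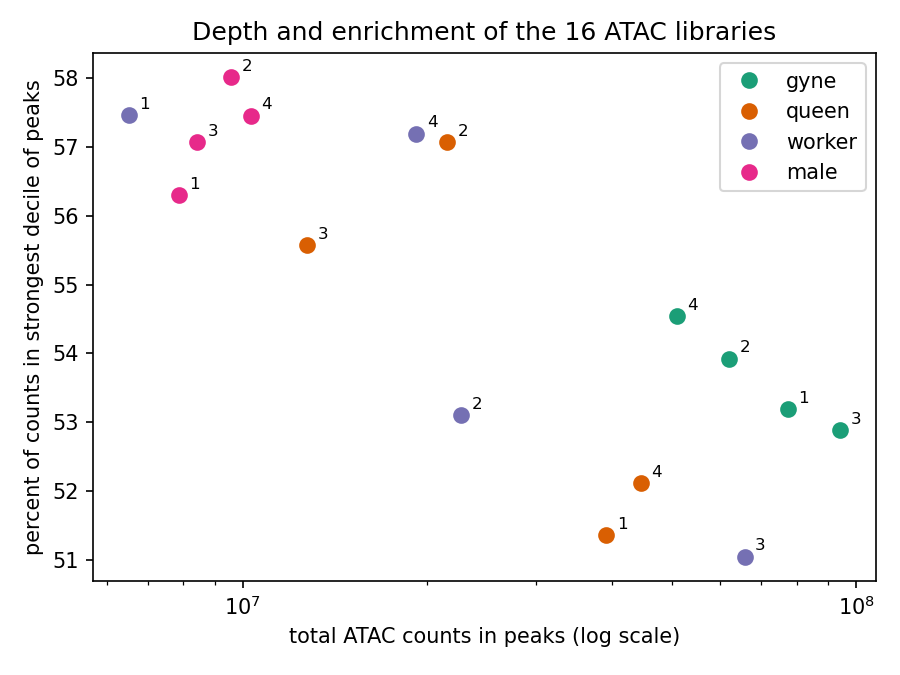
Counts in peaks (horizontal axis, log scale) and percent of counts in the strongest decile of peaks (vertical axis) of the 16 ATAC libraries, coloured by caste and numbered by replicate. The 4 male libraries held 7865588 to 10306212 counts, and worker libraries 1 and 4 lay above libraries 2 and 3 on the vertical axis.

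Queens and gynes are the same morphological caste after and before the start of reproduction. Venom allergen 2 (LOC105836896, NW_021021626.1, positions 6638284 to 6648151), named after a fire ant venom protein, had 59.0 ± 4.98 CPM in queens and 0.144 ± 0.0843 in gynes (log2 fold change 8.55 ± 0.145, adjusted p = 1.19e-19). Vitellogenin-2 was 7.01-fold higher in queens (818 ± 35.5 CPM, 2.81 ± 0.0631, adjusted p = 9.94e-18). LIRP, an insulin-related peptide (LOC105832901, NW_021020864.1, positions 76666 to 94271), rose from 2.86 ± 0.357 to 11.6 ± 0.652 CPM (2.02 ± 0.105, adjusted p = 9.95e-12). Small lysine-rich protein 1 (LOC105833312) was 21.3-fold lower in queens (-4.41 ± 0.113, adjusted p = 5.54e-17), and synapsin-3, a protein of synaptic vesicles (LOC105830664), 4.80-fold lower (-2.26 ± 0.0808, adjusted p = 1.6e-14).

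Further large rises in queens were in thyrotropin-releasing hormone-degrading ectoenzyme, a peptidase (LOC105837748, 3.73 ± 0.127), NPC intracellular cholesterol transporter 2, a sterol-binding protein (LOC105831241, 3.41 ± 0.0880), odorant-binding protein A10 (LOC105834049, 2.88 ± 0.0721) and maltase 1 (LOC105832682, 2.37 ± 0.0525). Falls were seen in piggyBac transposable element-derived protein 4 (LOC105828632, -1.72 ± 0.0589), fasciclin-1, a neural cell adhesion protein (LOC105836032, -1.40 ± 0.0562), and putative nuclease HARBI1, of transposase origin (LOC105830275, -1.24 ± 0.0492). The adjusted p of these 7 genes was at most 1.1e-13. Gustatory receptor 68a (LOC105832089) fell from 2.50 ± 0.279 to 0.112 ± 0.0962 CPM (-4.44 ± 0.318). Smaller differences were found in UDP-glucuronosyltransferase 2C1 (LOC105833950, 1.56 ± 0.0708), ecdysone receptor (LOC105840026, 0.29 ± 0.0280), protein yellow-like (LOC105839466, 0.88 ± 0.0946) and early growth response protein 1 (-0.27 ± 0.0286). Across all genes 1364 were higher in queens and 1098 lower, 118 and 95 of them by 2-fold or more.

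Fat body and yolk genes rose: of 20 measured, 10 were higher, 3 lower and 7 did not pass, the same adjusted over the list alone. As a set they passed camera at an adjusted p of 1.7e-06 (adjusted p = 0.0129 with an estimated correlation). Besides vitellogenin-2 the higher ones included vitellogenin-1 copies (LOC105832855, 1.34 ± 0.0632, and LOC105839512, 1.16 ± 0.0902) and apolipoprotein D (LOC105836565, 2.0 ± 0.0996). Cytosolic ribosomal proteins rose: of 79 measured, 43 were higher, 1 lower and 35 did not pass, with 56 higher and 1 lower adjusted over the list alone. The set test's adjusted p was 1.55e-14 (adjusted p = 0.387 with an estimated correlation). 60S ribosomal protein L7 (LOC105832889, 0.28 ± 0.0335) and L26 (LOC105829169, 0.41 ± 0.0633) were among the higher members. Photoreceptor genes rose: of 21 measured, 8 were higher, 1 lower and 12 did not pass, with 10 higher and 3 lower adjusted over the list alone. Their camera adjusted p was 0.00790 (adjusted p = 0.175 with an estimated correlation). The arrestin homolog (1.55 ± 0.0353) and an ultraviolet-sensitive opsin (LOC105836233, 1.30 ± 0.113) were higher, with the retina as their known site. Cytochrome P450 and detoxification genes rose: of 134 measured, 39 were higher, 12 lower and 83 did not pass, with 42 higher and 12 lower adjusted over the list alone. In camera the list had an adjusted p of 0.0159 (adjusted p = 0.369 with an estimated correlation). Examples were cytochrome P450 4g15 (LOC105834545, 0.148 ± 0.102 to 2.96 ± 0.317 CPM) and 4C1 (LOC105830266, 0.62 ± 0.0441). Neuropeptides and peptide hormones fell: of 26 measured, 6 were higher, 10 lower and 10 did not pass, the same adjusted over the list alone. Tested with camera, they had an adjusted p of 0.0279 (adjusted p = 0.369 with an estimated correlation). Their mean was 0.09 and their median -0.13. LIRP rose, while CAPA peptides (LOC105829981, -0.49 ± 0.0411), which act on insect kidney tubules, and myosuppressin (LOC105836520, -0.39 ± 0.0345) fell. The set test made no call for the lists of muscle (12 higher, 5 lower of 37), cuticle and epidermis (3 higher, 6 lower of 37), hemocyte (1 higher, 1 lower of 11), gut and salivary gland (8 higher, 6 lower of 36), glia (1 higher, 1 lower of 10) or mushroom body (1 higher, 2 lower of 19). The other 25 lists did not pass (adjusted p from 0.0555 to 0.965), and among them the median, mean and test differed in sign for fatty acid and hydrocarbon synthesis, gut and salivary gland and odorant-binding and chemosensory proteins.

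Between queens and gynes 3500 peaks were higher in queens and 4087 lower, and promoters held 22.4% of the higher and 12.4% of the lower peaks. The neprilysin-1 peak was lower in queens (1.87 ± 0.558 CPM, -2.26 ± 0.231, adjusted p = 5.59e-07), as was the RNA of that gene (-2.15). Peaks at chitin synthase chs-2 (LOC105831196, NW_021022222.1, positions 5131009 to 5131455, 2.0 ± 0.209), U3 small nucleolar RNA-associated protein 4 (LOC105831323, 1.94 ± 0.264) and serine protease nudel (LOC105830550, 1.83 ± 0.261) rose most, while chs-2 RNA was lower (-0.65), and those at an Ada-like DNA repair enzyme (LOC105831432, -1.56 ± 0.182) and glycogen synthase kinase-3 beta (LOC105830340, -1.51 ± 0.225) fell. A peak 793 bp from the LIRP start (NW_021020864.1, positions 92829 to 93478) was less accessible in queens (-0.97 ± 0.180, adjusted p = 0.000456), while LIRP RNA was higher, and a titin peak (LOC105835798, NW_021015332.1, positions 16782614 to 16784071) fell (-0.52 ± 0.112) while its RNA rose (0.36). Of 3 peaks called at genes named for their RNA and called in it, 1 shared the RNA direction and 2 did not. The counts of higher and lower peaks moved with the processing. They were 9514 and 9688 with limma voom and quality weights and 7931 and 7527 with quantile normalization. With only the 2 castes in the fit they were 5473 and 6311. Added after the data were seen, the share in the strongest decile of peaks as a covariate gave 5802 and 6247. Higher peaks numbered 2197 with all libraries thinned to the total of the shallowest, another added alternative, and 2145, 2212 and 2199 without gyne replicates 2, 3 and 4.

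Queens and workers, the reproductive and the sterile females, differed most in vitellogenin-2, at 818 ± 35.5 against 1.72 ± 0.578 CPM (log2 fold change 8.89 ± 0.0984, adjusted p = 2.6e-23), and in venom allergen 2 (LOC105836896, 8.84 ± 0.149, adjusted p = 2.63e-20). A second gene of that name (LOC105831944) was 7.33-fold higher (2.87 ± 0.117). The arrestin homolog stood at 113 ± 1.86 CPM in queens and 16.7 ± 1.09 in workers (2.76 ± 0.0385, adjusted p = 1.31e-21). Workers had more collagen alpha-1(II) chain (-3.38 ± 0.0749), glycine-rich cell wall structural protein 1.8 (-3.21 ± 0.0865), ras-related and estrogen-regulated growth inhibitor (-2.84 ± 0.0734), small lysine-rich protein 1 (-2.81 ± 0.122) and synapsin-3 (-2.21 ± 0.0810), with adjusted p of at most 1.45e-13. Early growth response protein 1 was 3.58-fold lower in queens (-1.84 ± 0.0286, adjusted p = 7.33e-21), and pro-corazonin 3.14-fold lower (-1.65 ± 0.0882, adjusted p = 4.01e-12).

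Thyrotropin-releasing hormone-degrading ectoenzyme (3.26 ± 0.119), hypertrehalosaemic prohormone (2.24 ± 0.0652), glycine receptor alpha-3 (1.99 ± 0.0486), LIRP (1.48 ± 0.0992), antichymotrypsin-2, a protease inhibitor (LOC105838223, 0.81 ± 0.0287), cytochrome P450 6j1-like (LOC105836517, 0.89 ± 0.0403), neuropeptide SIFamide receptor (0.79 ± 0.0398) and odorant-binding protein 59a (LOC105831315, 0.53 ± 0.0284) were higher in queens. Synaptotagmin-10-like (-0.92 ± 0.0302), voltage-dependent calcium channel type A (-0.85 ± 0.0356), tyramine receptor 2 (-0.67 ± 0.0304), inositol 1,4,5-trisphosphate receptor (-0.61 ± 0.0291) and acidic mammalian chitinase (LOC105833228, -0.51 ± 0.0264) were lower. Of all genes tested, 3352 were higher in queens and 2923 lower, 167 and 319 of them by 2-fold or more.

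Between queens and workers 13 of the 30 lists passed, and all 13 calls were lost with an estimated correlation. Mushroom body genes fell: of 19 measured, 0 were higher, 18 lower and 1 did not pass, the same adjusted over the list alone. Camera gave them an adjusted p of 5.03e-10 (adjusted p = 0.118 with an estimated correlation). Neuropeptides and peptide hormones fell: of 26 measured, 6 were higher, 16 lower and 4 did not pass, the same adjusted over the list alone. As a set they passed camera at an adjusted p of 0.000296 (adjusted p = 0.118 with an estimated correlation). Myosuppressin (-0.83 ± 0.0344), diuretic hormone 44 (-0.74 ± 0.0306) and CAPA peptides (-0.97 ± 0.0411) were among the lower. Biogenic amine genes fell: of 29 measured, 4 were higher, 14 lower and 11 did not pass, with 4 higher and 15 lower adjusted over the list alone. The set test's adjusted p was 0.00137 (adjusted p = 0.118 with an estimated correlation). Synaptic vesicle and release genes fell: of 55 measured, 14 were higher, 26 lower and 15 did not pass, with 16 higher and 26 lower adjusted over the list alone. Their camera adjusted p was 0.0397 (adjusted p = 0.118 with an estimated correlation). Transmitter receptors fell: of 61 measured, 12 were higher, 25 lower and 24 did not pass, with 12 higher and 27 lower adjusted over the list alone. In camera the list had an adjusted p of 0.0401 (adjusted p = 0.255 with an estimated correlation). Peptide hormone receptors fell: of 31 measured, 4 were higher, 15 lower and 12 did not pass, the same adjusted over the list alone. Tested with camera, they had an adjusted p of 0.0397 (adjusted p = 0.199 with an estimated correlation). Insulin receptor (LOC105839953, -0.44 ± 0.0304) was among the lower. Odorant and taste receptors fell: of 131 measured, 7 were higher, 43 lower and 81 did not pass, with 6 higher and 36 lower adjusted over the list alone. Camera gave them an adjusted p of 0.0271 (adjusted p = 0.429 with an estimated correlation). The last 4 calls were also lost without worker replicate 4, with adjusted p of 0.0576, 0.0576, 0.0696 and 0.0506 in that order, and that of transmitter receptors without queen replicate 4 as well (adjusted p = 0.0550). Learning and activity-dependent genes fell: of 8 measured, 1 was higher, 4 lower and 3 did not pass, the same adjusted over the list alone. As a set they passed camera at an adjusted p of 0.0271 (adjusted p = 0.255 with an estimated correlation). Cytosolic ribosomal proteins rose: of 79 measured, 65 were higher, 0 lower and 14 did not pass, with 67 higher and 0 lower adjusted over the list alone. The set test's adjusted p was 5.87e-16 (adjusted p = 0.373 with an estimated correlation). Cell cycle and DNA replication genes rose: of 33 measured, 21 were higher, 0 lower and 12 did not pass, with 22 higher and 0 lower adjusted over the list alone. Their camera adjusted p was 0.000592 (adjusted p = 0.118 with an estimated correlation).

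Among the tissue-marker lists, 3 passed. Photoreceptor genes rose: of 21 measured, 9 were higher, 5 lower and 7 did not pass, with 10 higher and 5 lower adjusted over the list alone. In camera the list had an adjusted p of 0.0394 (adjusted p = 0.199 with an estimated correlation). Fat body and yolk genes rose: of 20 measured, 11 were higher, 2 lower and 7 did not pass, with 12 higher and 2 lower adjusted over the list alone. Tested with camera, they had an adjusted p of 0.0271 (adjusted p = 0.164 with an estimated correlation). Apolipophorins, the lipid carrier of insect blood (LOC105829368, 0.86 ± 0.0456), were among the higher. Muscle genes fell: of 37 measured, 6 were higher, 20 lower and 11 did not pass, the same adjusted over the list alone. Camera gave them an adjusted p of 0.0271 (adjusted p = 0.236 with an estimated correlation). The set test made no call for the lists of cuticle and epidermis (9 higher, 11 lower of 37), hemocyte (1 higher, 5 lower of 11), gut and salivary gland (9 higher, 13 lower of 36) or glia (3 higher, 4 lower of 10). The other 17 lists did not pass (adjusted p from 0.0534 to 0.967), and the median, mean and test differed in sign for circadian clock, fatty acid and hydrocarbon synthesis, glia, gut and salivary gland, juvenile hormone and ecdysteroid and odorant-binding and chemosensory proteins.

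In accessibility, 4071 peaks were higher in queens than workers and 4077 lower, with promoters holding 12.2% and 19.8% of them. That order turned without worker libraries 1 and 4 (16.2% and 6.66%) and without worker replicate 4 alone (13.4% and 11.5%), and that of the lower peaks was 12.5%, 11.8%, 11.9% and 38.1% without queen replicates 1 and 4 and worker replicates 1 and 3. A peak at the start of doublesex- and mab-3-related transcription factor A2, of the family of sexual differentiation factors (LOC105835522, NW_021017526.1, positions 71 to 1038), had 92.1 ± 2.89 CPM in queens and 42.1 ± 4.22 in workers (1.12 ± 0.130, adjusted p = 3.34e-06), while its RNA did not pass. Peaks rose at glycine receptor alpha-3 (1.43 ± 0.172), band 4.1-like protein 4 (2.22 ± 0.290), cyclin-dependent kinase 4 (2.12 ± 0.253) and carboxypeptidase M (LOC105830622, 1.83 ± 0.235), and fell at tachykinins (LOC105833215, NW_021021626.1, positions 13366740 to 13367022, -1.80 ± 0.313), glycogen synthase kinase-3 beta (-1.67 ± 0.232) and polyubiquitin-B (LOC105829042, -1.64 ± 0.226). RNA fell as well at tachykinins (-0.88), glycogen synthase kinase-3 beta (-0.74) and polyubiquitin-B (-0.34), but carboxypeptidase M RNA was lower (-0.80), opposite to its peak. Of 11 peaks called at genes named for their RNA and called in it, 9 shared the RNA direction and 2 did not. LIRP's 793 bp peak opposed it (-1.20 ± 0.185, RNA 1.48). Limma voom with quality weights (worker 2 highest) called 8308 higher and 10438 lower peaks, and edgeR without worker libraries 1 and 4 2116 and 1697. Lower peaks numbered 6357 and 2581 without worker replicates 3 and 4. Another split of these 8 libraries, queen 1, 3 and 4 with worker 3 against the rest, gave 8488 calls, against 8148 for the castes. Queen 1 and 4 and worker 3 had the lowest shares in the strongest decile of peaks (51.4%, 52.1% and 51.0%, the others 53.1% to 57.5%), and with that share as a covariate the castes gave 5624 higher and 5971 lower.

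Males differed from gynes, the winged reproductive female, more than any female caste differed from another in number of calls: 4244 genes were higher in males and 4016 lower, 732 and 487 by 2-fold or more. Major royal jelly protein 1 (LOC105829554, NW_021016313.1, positions 10252186 to 10254747), of the family that includes the main honeybee royal jelly protein, had 48.6 ± 2.42 CPM in males and 0.833 ± 0.263 in gynes (log2 fold change 5.82 ± 0.119, adjusted p = 2.45e-19). The arrestin homolog (LOC105833829, NW_021022222.1, positions 9035924 to 9038712) reached 429 ± 8.57 CPM against 38.5 ± 0.574 (3.48 ± 0.0363, adjusted p = 8.05e-24). Polycomb protein suz12-B (LOC105831809, NW_021023680.1, positions 786736 to 794216), a subunit of the complex that methylates histone H3 lysine 27, had 69.0 ± 2.06 CPM in males and 359.8 ± 6.32 in gynes (-2.38 ± 0.0297, adjusted p = 1.39e-22). Vitellogenin-2 was 84.6-fold lower in males (-6.40 ± 0.105, adjusted p = 1.28e-20) and transferrin, an iron-binding protein (LOC105833024), 6.43-fold lower (-2.68 ± 0.0410, adjusted p = 5.13e-21). Glutamine synthetase 2 (LOC105838474), which glia use to recycle glutamate, stood at 3959 ± 71.2 against 1652 ± 41.8 CPM (1.26 ± 0.0295, adjusted p = 2.14e-18).

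Prostatic acid phosphatase (LOC105830574, 3.78 ± 0.0605), inositol oxygenase, the first enzyme of inositol breakdown (LOC105832069, 3.70 ± 0.0673), probable chitinase 10 (LOC105837245, 3.27 ± 0.145), vesicular glutamate transporter 2 (LOC105835394, 2.63 ± 0.0619), peptidoglycan-recognition protein SC2, of innate immunity (LOC105835677, 2.05 ± 0.0517), heat shock 70 kDa protein cognate 4 (LOC105838616, 1.77 ± 0.0458), a G protein-activated inward rectifier potassium channel (LOC105835508, 1.57 ± 0.0383), GABA transporter 1, which clears that transmitter (LOC105835702, 1.47 ± 0.0363), and NADPH--cytochrome P450 reductase (LOC105839525, 1.36 ± 0.0279) rose in males. Small lysine-rich protein 1 (-4.36 ± 0.113), transmembrane protein 26 (LOC105836748, -3.07 ± 0.0738), toll-like receptor 3 (LOC114254607, -2.67 ± 0.0942), CAPA peptides (-2.60 ± 0.0452), neuroparsin-A, a neurohormone (LOC105837629, -2.13 ± 0.0571), and short neuropeptide F (LOC105838249, -1.34 ± 0.0275) fell. The adjusted p of these 15 genes was at most 5.04e-14. Pro-corazonin was 2.63-fold higher in males (1.40 ± 0.0876), at 166 ± 22.8 CPM.

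Oxidative phosphorylation genes rose: of 64 measured, 58 were higher, 3 lower and 3 did not pass, the same adjusted over the list alone. As a set they passed camera at an adjusted p of 2.06e-18 (adjusted p = 0.132 with an estimated correlation). Cytochrome b-c1 complex subunit 7 (LOC105839264, 1.22 ± 0.0315), ATP synthase subunit d (LOC105834765, 0.98 ± 0.0315) and subunit O (LOC105835001, 0.94 ± 0.0310) were among the higher. Chromatin modifiers fell: of 79 measured, 20 were higher, 39 lower and 20 did not pass, the same adjusted over the list alone. The set test's adjusted p was 0.00676 (adjusted p = 0.0512 with an estimated correlation). Besides suz12-B, histone-lysine N-methyltransferase KMT5B (LOC105830481, -1.47 ± 0.0365), lysine-specific demethylase 6A, which removes histone H3 lysine 27 methylation (LOC105831887, -2.01 ± 0.0756), and histone deacetylase 5 (LOC105833781, -0.57 ± 0.0248) fell. Mushroom body genes fell: of 19 measured, 1 was higher, 14 lower and 4 did not pass, the same adjusted over the list alone. Their camera adjusted p was 0.00463 (adjusted p = 0.559 with an estimated correlation). Kenyon cell-specific protein 1 changed by -1.10 ± 0.0520. Cytosolic ribosomal proteins fell: of 79 measured, 8 were higher, 41 lower and 30 did not pass, the same adjusted over the list alone. In camera the list had an adjusted p of 0.0109 (adjusted p = 0.850 with an estimated correlation).

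Of the lists of other tissues, muscle passed the set test. Muscle genes rose: of 37 measured, 26 were higher, 5 lower and 6 did not pass, the same adjusted over the list alone. Tested with camera, they had an adjusted p of 0.000697 (adjusted p = 0.132 with an estimated correlation). Troponin C, the calcium sensor of muscle (LOC105831647), went from 6.70 ± 0.509 to 36.0 ± 0.763 CPM, while a myosin light chain alkali (LOC105835909, -1.61 ± 0.0689) fell. Photoreceptor genes missed the threshold as a list (11 higher, 6 lower of 21, adjusted p = 0.0511), but the arrestin homolog rose (3.48 ± 0.0363). The set test made no call for the lists of fat body and yolk (11 higher, 4 lower of 20), cuticle and epidermis (14 higher, 12 lower of 37), hemocyte (4 higher, 3 lower of 11), gut and salivary gland (9 higher, 8 lower of 36) or glia (7 higher, 3 lower of 10). The other 25 lists did not pass (adjusted p from 0.0511 to 0.967), and the median, mean and test differed in sign for cuticle and epidermis, gut and salivary gland, hemocyte, odorant-binding and chemosensory proteins, sex determination and synaptic vesicle and release. All 5 calls of lists were lost with an estimated correlation.

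Between males and gynes 7760 peaks were higher in males and 7663 lower, and promoters held 28.7% of the higher and 10.5% of the lower peaks, an order that turned with the share of counts in the strongest decile of peaks as a covariate (18.3% and 26.4%). A peak 203 bp from a start of cyclin-dependent kinase-like 4 (LOC105829632, NW_021015483.1, positions 24879 to 25138) had 0.356 ± 0.0872 CPM in males and 3.39 ± 0.631 in gynes (-3.24 ± 0.335, adjusted p = 5.39e-08), and its RNA differed by -2.16. The peak at tachykinins fell (-3.07 ± 0.464), as did its RNA (-0.43), and so did one at cyclic pyranopterin monophosphate synthase-like (LOC105828339, -2.96 ± 0.364). Peaks at vicilin-like seed storage protein At2g18540 (LOC105829965, 2.85 ± 0.423), THAP domain-containing protein 1 (2.32 ± 0.321) and chitin synthase chs-2 (2.22 ± 0.220) rose most, but RNA of the THAP gene was lower (-0.60), opposite to its peak. The 3 peaks called at genes named for their RNA and called in it, which leave out such peaks, shared the RNA direction. Scaled to total counts in peaks without TMM (edgeR's trimmed mean normalization), 4539 higher and 9760 lower peaks were called, with the median over all peaks shifted by -0.16 (log2; -0.16 for male against queen). Male libraries held 56.3% to 58.0% of their counts in the strongest decile of peaks and gyne libraries 52.9% to 54.5%.

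Genes known from work on caste and sex were followed whether or not they passed. Among 7 vitellogenin genes the most abundant, vitellogenin-1 (LOC105832806), had 1837 ± 47.5 CPM in gynes, 2224 ± 78.5 in queens, 1814 ± 40.3 in workers and 1459 ± 35.4 in males, higher in queens than gynes by 0.28 ± 0.0298. Another copy (LOC105839517) changed by 0.77 ± 0.0768 in queens and -1.03 ± 0.0921 in males against gynes, and vitellogenin (LOC105833878) and vitellogenin-1-like (LOC114254889) were below 4 CPM in every caste. Krueppel homolog 1, the juvenile hormone response factor (LOC105831787), was lower in gynes than workers (-0.39 ± 0.0435) and lower in males than gynes (-0.73 ± 0.0438), while the log2 fold changes of a second gene of that name (LOC105837684) were -0.23 ± 0.0642 and 0.08 ± 0.0648 in these comparisons, adjusted p = 0.00621 and 0.302. The doublesex-related factor at LOC105837800 was lower in gynes than workers (-0.54 ± 0.0345) and lower in males than gynes (-0.37 ± 0.0347), whereas the A2 factor (LOC105835522) passed in none of the 4 main comparisons (lowest adjusted p 0.0876). Another such factor (LOC105833732) was at 3.01 ± 0.135 CPM in gynes and 4.25 ± 0.426 in workers (adjusted p = 0.00166). Bombyxin B-5 (LOC105840254) rose in queens against gynes (0.32 ± 0.0662, adjusted p = 0.00147) and did not pass between males and gynes (adjusted p = 0.690). Neuroparsin-A was lower in gynes than workers (-0.50 ± 0.0503), and LIRP lower in males than gynes (-1.36 ± 0.153). How reads shared by the vitellogenin copies were counted is not given in the sources used here, and neither is the use of strand, so values of copies and of overlapping genes are uncertain.

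Males were also compared with the reproductive and the sterile females. Against queens, major royal jelly protein 1 (5.82 ± 0.119) and branched-chain-amino-acid aminotransferase, an enzyme of amino acid breakdown (LOC105834878, 4.06 ± 0.0833), were most raised in males, and vitellogenin-2 (-9.21 ± 0.102) and venom allergen 2 (LOC105836896, -5.26 ± 0.102) most lowered. Against workers, major royal jelly protein 1 (7.81 ± 0.148) and the arrestin homolog (4.68 ± 0.0395) were highest and ATP-binding cassette sub-family G member 1 (LOC105837609, -3.18 ± 0.0647) and CAPA peptides (-3.08 ± 0.0456) lowest. Counts were 4268 genes higher and 4216 lower against queens, and 4549 and 4588 against workers. Chromatin modifiers, against queens, fell: of 79 measured, 18 were higher, 41 lower and 20 did not pass, the same adjusted over the list alone. Tested with camera, they had an adjusted p of 0.00467 (adjusted p = 0.0413 with an estimated correlation). Oxidative phosphorylation genes, against queens, rose: of 64 measured, 59 were higher, 3 lower and 2 did not pass, the same adjusted over the list alone. Camera gave them an adjusted p of 7.28e-18 (adjusted p = 0.201 with an estimated correlation). Oxidative phosphorylation genes, against workers, rose: of 64 measured, 59 were higher, 1 lower and 4 did not pass, the same adjusted over the list alone. As a set they passed camera at an adjusted p of 4.52e-16 (adjusted p = 0.265 with an estimated correlation). Against queens the muscle list also rose (camera adjusted p = 0.00386, adjusted p = 0.261 with an estimated correlation) and the mushroom body (camera adjusted p = 0.0119, adjusted p = 0.553 with an estimated correlation) and cytosolic ribosomal lists (camera adjusted p = 3.45e-08, adjusted p = 0.648 with an estimated correlation) fell. Against workers the mushroom body (camera adjusted p = 2.84e-05, adjusted p = 0.307 with an estimated correlation) and neuropeptide lists (camera adjusted p = 0.00615, adjusted p = 0.307 with an estimated correlation) fell. Peaks called were 5796 higher and 6342 lower against queens, and 9169 and 9181 against workers. Against queens, limma voom with quality weights called 9792 higher and 8339 lower peaks, and total counts without TMM 3389 and 8721.

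Gynes and queens were each compared with the same 4 worker libraries. Of 12375 genes, 2306 were higher and 2083 lower in both than in workers, among them hypertrehalosaemic prohormone and glycine receptor alpha-3 (higher) and collagen alpha-1(II) chain and early growth response protein 1 (lower), while 124 were called in opposite directions. Independent lists of these lengths would share 827 and 688. In 20 simulations of unchanged groups against the same workers, 0 and 0.05 genes were shared on average. Groups without changed genes give hardly any calls, so these simulations cannot say how much the common workers add to the overlap of changed genes. With the workers split into 2 and 2, 1747 to 1836 genes were higher and 1419 to 1497 lower in both over the 6 splits. The fold changes correlated across genes at r = 0.648 (simulated 0.501), genes not being independent replicates, and their covariance was 0.119 against a simulated 0.00845, a difference of 0.111.

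RNA and accessibility were related across the 8539 genes with a peak within 1 kb of a transcript start. Neprilysin-1, Rx1, glycine receptor alpha-3 and tachykinins differed the same way in both, while LIRP (peak at 793 bp) in queens against gynes, carboxypeptidase M in queens against workers and THAP domain-containing protein 1 in males against gynes differed in opposite ways. Spearman's rho between the fold changes was -0.0539 for gyne against worker, 0.0838 for queen against gyne, -0.0274 for queen against worker, 0.0551 for male against gyne, 0.0797 for male against queen and 0.0765 for male against worker. Genes are not independent replicates, and other splits of the ATAC libraries gave values as large in 7 to 28 of 35 splits, the real one included, so chance could not be excluded for any of the 6. Leaving out 1 replicate at a time, rho ran from -0.0847 without worker replicate 3 to -0.0293 without worker replicate 4 for gyne against worker. For queen against worker it ran from -0.0653 without worker replicate 3 to 0.00842 without worker replicate 4, and was 0.00780 without queen replicate 4. Pairs of a called gene and a called peak within 1 kb of its start were counted, so a gene with several such peaks counts more than once. Of these pairs, 604 had the same and 816 the opposite direction between gynes and workers, 197 and 132 between queens and gynes, 457 and 400 between queens and workers, and 1364 and 1097 between males and gynes.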

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

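The patterns weighed here were chosen after the data were seen, and the muscle test and the test relative to other genes of oxidative phosphorylation genes and the fat body and copy tests of vitellogenin-2 were chosen only after the values they rest on had been seen. Of 316 groups of 4 libraries examined, 18 had 1 library whose gap to the nearest other exceeded Dixon's critical value, and chance gives about 1 in 20 groups.

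Gyne replicate 1 stood apart from the other 3 gyne libraries in ras-related and estrogen-regulated growth inhibitor (LOC105835388) 41.3 CPM against 36.3 to 37.1. Male replicate 1 stood apart from the other 3 male libraries in Krueppel homolog 1 (LOC105831787) 557 CPM against 494 to 499. Male replicate 2 stood apart from the other 3 male libraries in voltage-dependent calcium channel type A subunit alpha-1 (LOC105833674) 266 CPM against 277 to 278 and cytochrome P450 6j1-like (LOC105836517) 109 CPM against 104 to 104. Male replicate 4 stood apart from the other 3 male libraries in glutamine synthetase 2, cytoplasmic (LOC105838474) 3853 CPM against 3981 to 4002. Queen replicate 1 stood apart from the other 3 queen libraries in vesicular glutamate transporter 2 (LOC105835394) 20.8 CPM against 22.4 to 22.6 and sodium- and chloride-dependent GABA transporter 1 (LOC105835702) 307 CPM against 279.7 to 281. Queen replicate 3 stood apart from the other 3 queen libraries in voltage-dependent calcium channel type A subunit alpha-1 (LOC105833674) 372 CPM against 386 to 388 and antichymotrypsin-2 (LOC105838223) 146 CPM against 141 to 142. Queen replicate 4 stood apart from the other 3 queen libraries in collagen alpha-1(II) chain (LOC105833881) 8.73 CPM against 9.98 to 10.2. Worker replicate 1 stood apart from the other 3 worker libraries in cysteine sulfinic acid decarboxylase (LOC105836112) 33.0 CPM against 25.1 to 26.3, collagen alpha-1(II) chain (LOC105833881) 110.2 CPM against 96.8 to 98.1, neuroparsin-A (LOC105837629) 137 CPM against 116 to 118, vitellogenin-1 (LOC105832806) 1755 CPM against 1829 to 1842, inositol 1,4,5-trisphosphate receptor (LOC105835203) 1243 CPM against 1153 to 1159 and transferrin (LOC105833024) 345 CPM against 311 to 312. Worker replicate 4 stood apart from the other 3 worker libraries in vitellogenin-2 (LOC105835926) 2.58 CPM against 1.39 to 1.49 and probable chitinase 10 (LOC105837245) 1.63 CPM against 1.94 to 1.98.

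Promoter peaks differed from other peaks by -0.237 on the log2 scale in gynes against workers, short of the threshold (exact permutation p = 0.286, n = 4 per caste), and by 0.203 in males against gynes (exact permutation p = 0.0286). Thinning all ATAC libraries to equal depth lowers every peak of a library alike, so it cannot decide on depth. Depth stays open in both comparisons, and male libraries were all shallower than gyne libraries. After thinning the differences were -0.229 and 0.195 (exact permutation p = 0.286 and 0.0286). At matched peak height, a correction for enrichment, they were -0.154 (exact permutation p = 0.0286) and 0.0860 (exact permutation p = 0.0857), so a difference in enrichment between libraries may account for part of the male difference, of which 42.3% remained, and stays open for gynes and workers with 64.9% left. Enrichment and caste cannot be told apart for males, whose libraries (56.3% to 58.0% of counts in the strongest decile of peaks) did not overlap those of gynes (52.9% to 54.5%): the bound set beforehand counted a lost call against caste, but a p that misses the threshold does not show that the difference is gone. Among workers the promoter difference was 0.348 and 0.421 in libraries 1 and 4 and -0.0703 and -0.291 in libraries 2 and 3. Without libraries 1 and 4 the difference from gynes over all peaks turned to 0.0452, but did not turn at matched height. Caste stays open for gynes and workers too.

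Oxidative phosphorylation genes were higher in males, 58, 59 and 59 of 64 against gynes, queens and workers, with summed CPM of 12783 ± 499 in males, 7529 ± 70.7 in gynes, 7820.5 ± 114 in queens and 7651 ± 319.7 in workers (n = 4 each). Muscle carried with male brains stays open: the muscle list had a median log2 fold change of 0.811, 0.721 and 0.335 (smallest 0.335) beside 0.749, 0.675 and 0.706 for oxidative phosphorylation, while its summed CPM rose by 2.83%, 2.09% and 2.13% as much, and the share muscle would add of each was not measured. The highest median of 1000 random lists matched on transcript length was 0.383 over the 3 comparisons, below all 3 medians of the list, which argues against length. One scaling factor per library moves all genes alike, and the list's median lay at least 0.292 above the highest of those random lists in the same comparison, which argues against normalization as the source of the rise relative to other genes. The level itself stays open, since DESeq2 size factors and voom with quality weights (100% as many members called higher in the comparison with the fewest) moved the median of all genes by at most 0.00348 (log2) and so tested no other scaling, and so do the makeup of cell types and an untested difference between male and female brains.

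Vitellogenin-2 was higher in queens than gynes by 2.81 on the log2 scale, and by at least 2.78 without any 1 of the 8 libraries, which argues against a single library. The other 6 vitellogenin genes summed to 414 CPM more in queens while vitellogenin-2 gained 701 CPM, which argues against reads moved from the copies to it. Fat body carried with queen brains could add yolk protein RNA: 8 other fat body members below 10 CPM in gynes had a median of 0.320, from -0.92 to 2.0 (SD 0.915). That spread reaches past the bound set for fat body, 0.702, so fat body stays open, and 9 members were already at 10 CPM or more in gyne brains. Reproductive state, the difference the design names, stays open and untested.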

How the results depend on the processing

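Thinning to equal depth, the enrichment covariate, ATAC without worker libraries 1 and 4, quantile-normalized values in the relation of RNA and accessibility, lists without 3 members, and all alternatives of the promoter shares of peaks were chosen only after the data were seen. No called result changed direction under any alternative run. The promoter percentage of higher peaks minus that of lower peaks, which has no test of its own, did: gyne against worker went from -27.6 to 6.47 percentage points and queen against worker from -7.56 to 9.55 without worker libraries 1 and 4 (from -26.6 without worker replicate 3 to 1.83 without worker replicate 4), and male against gyne from 18.2 to -8.11 with the enrichment covariate and, in the same direction, 4.54 with quantile normalization. With DESeq2, its size factors in edgeR and no low-count filter, all 13 RNA and 13 ATAC counts of calls stayed within 1.5 times, as did the RNA counts with voom and quality weights, and the 4-caste counts in every alternative run. Of named genes, 17 of the values under alternatives fell short of the threshold and 10 passed it newly, most of them on leaving out 1 replicate (tachykinins and vitellogenin in queen against gyne, vitellogenin and LOC105833732 in male against gyne, and vitellogenin-1 LOC105832855 and bombyxin B-5 in queen against worker lost calls), while all 35 named peaks kept their call and direction throughout. A 2-fold minimum, which removes smaller changes by construction, left 117 and 192, 118 and 95, 167 and 319, 732 and 487, 771 and 493, 862 and 770 RNA genes (higher and lower), and 1267 and 556, 520 and 797, 1082 and 986, 1486 and 3337, 1000 and 2387, 3161 and 3943 peaks, for gyne against worker, queen against gyne, queen against worker, male against gyne, male against queen and male against worker. The cause was not tested for the following ATAC counts. Voom with quality weights (worker 2 highest) called 10184 higher and 11807 lower peaks (gyne against worker), 9514 and 9688 (queen against gyne), 8308 and 10438 (queen against worker) and 9792 higher (male against queen). Quantile normalization gave 8054 and 8507, then 7931 and 7527, for the first and second of these. Only the 2 castes in the fit gave 5473 and 6311 for queen against gyne. Total counts without TMM gave 4539 and 9760 for male against gyne and 3389 and 8721 for male against queen. Equal depth left 2197 peaks higher in queens than gynes, and the enrichment covariate 5802 higher and 6247 lower. Without worker libraries 1 and 4, fewer samples by construction, queen against worker gave 2116 higher and 1697 lower. Leaving out 1 replicate at a time gave 2705 to 6241 peaks lower in gynes than workers, 2145 to 3370 higher in queens than gynes and 2581 to 6357 lower in queens than workers, while the other RNA and ATAC counts stayed within 1.5 times. Lists past camera numbered 0, 1, 0, 0, 1 and 0 in the same order of comparisons with an estimated correlation (7, 3, 7, 4, 4 and 3 at an unadjusted p below 0.05), in place of 6, 5, 13, 5, 5 and 3, and leaving out 3 members changed no number. The Spearman correlation of RNA and accessibility for male against queen was 0.130 with the enrichment covariate, for male against gyne 0.0836 with it and 0.0677 with quantile normalization, and for male against worker 0.107 with quantile normalization. None of these added values was set against other splits. The replicate number did not pair the libraries by the criterion that every same-number correlation exceed 0.1: deviations of libraries with the same number correlated at -0.128 to 0.279 for RNA (above 0.1 in 3 of 24 pairs) and -0.362 to 0.320 for ATAC (4 of 24), and 8 and 3 of 16 libraries were closest to their own number. As a hint from the data, not the design, RNA replicate 1 had the highest score of its caste on the fourth principal component in all 4 castes (4.45 in gynes, 6.44 in queens, 16.3 in workers, 12.4 in males). With the number as a replicate block, 1666 genes were higher in queens than gynes and 1374 lower, no count moved by over 1.5 times, and of the list calls photoreceptor genes in queen against worker were not called (adjusted p = 0.0598). In simulated gyne and worker data 24% of 1.5-fold changes of peaks were recovered, against 82% of genes, with a biological coefficient of variation of 16.6% for ATAC and 4.83% for RNA, and whether depth or this spread limits ATAC was not tested there.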

Other observations

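The tests of other splits and groupings were set beforehand, except the comparison of single lists with other splits, which was chosen only after the results were seen. Gene lists without a passing set test in any of the 4 main comparisons held single genes that differed. Circadian clock genes in males against gynes (2 higher and 6 lower of 10, the same counts adjusted over the list alone, camera adjusted p = 0.452) included period circadian protein (LOC105835224, 1.39 ± 0.0693), the repressor of the clock feedback loop, and cryptochrome-1 (LOC105837924, -1.13 ± 0.0705), its light- or clock-linked partner. Cryptochrome-1 was also lower in gynes (-0.84 ± 0.0607) and queens (-1.13 ± 0.0622) than in workers. Juvenile hormone and ecdysteroid genes in males against gynes (7 higher and 11 lower of 28, the same counts adjusted over the list alone, camera adjusted p = 0.383) included a juvenile hormone acid O-methyltransferase (LOC105837575, -2.78 ± 0.170), of the enzyme family that completes juvenile hormone, and broad-complex core protein (LOC105832392, -0.94 ± 0.0466). Heat shock genes and chaperones (25 higher and 8 lower of 45, the same counts adjusted over the list alone, camera adjusted p = 0.0914) included protein lethal(2)essential for life-like (LOC105837298, 2.04 ± 0.102), a small heat shock protein that was higher in queens than workers as well (1.53 ± 0.133). Immunity genes in males (18 higher and 9 lower of 36, the same counts adjusted over the list alone, camera adjusted p = 0.421) included toll-like receptor 6 (LOC105836851, 1.90 ± 0.0778) and peptidoglycan-recognition protein LC (LOC105834280, 0.76 ± 0.0464). Insulin and TOR genes (13 higher and 8 lower of 36, the same counts adjusted over the list alone, camera adjusted p = 0.535) included the GTPase Rheb (LOC105837142, 0.66 ± 0.0351) and insulin receptor substrate 1 (LOC105833897, 0.55 ± 0.0375). Yellow and royal jelly proteins (5 higher and 4 lower of 15, the same counts adjusted over the list alone, camera adjusted p = 0.710) included major royal jelly protein 1 and protein yellow (LOC105835385, -1.14 ± 0.0979).

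Odorant-binding and chemosensory proteins in queens against gynes (8 higher and 5 lower of 19, 8 and 6 adjusted over the list alone, camera adjusted p = 0.189) included pheromone-binding protein Gp-9 (LOC105835869, 1.66 ± 0.189) and ejaculatory bulb-specific protein 3 (LOC105834922, 1.29 ± 0.101), of the chemosensory protein family. In queens against workers another Gp-9 gene was lower (LOC105828122, -2.34 ± 0.174). Fatty acid and hydrocarbon synthesis genes in queens against workers (10 higher and 9 lower of 44, the same counts adjusted over the list alone, camera adjusted p = 0.967) included fatty acyl-CoA reductase 1 (LOC105840716, 3.00 ± 0.166), which was also higher in gynes than workers (2.64 ± 0.172). Sex determination genes in gynes against workers (0 higher and 3 lower of 5, the same counts adjusted over the list alone, camera adjusted p = 0.0582) included a sex-lethal homolog (LOC105834952, -0.26 ± 0.0255).

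Counts of calls were compared with other splits of the same libraries. For RNA, the real split of each pair of castes came first of 35. Calls were 5965 in gyne against worker (highest other 0), 2462 in queen against gyne (79) and 6275 in queen against worker (0). They were 8260 in male against gyne (0), 8484 in male against queen (0) and 9137 in male against worker (0). Rank 1 of 35 is the most this test can show, and mixing castes widens the spread in other splits, so chance is not excluded. Among 100 groupings drawn for the 4-caste test none other reached 10533 genes (highest other 2275). Of 60 groupings for peaks none other reached 23559 (highest other 1). For peaks the real split also came first in gyne against worker (9589 calls, highest other 1), queen against gyne (7587, 0) and male against gyne (15423, 0). So it did in male against queen (12138, 236) and male against worker (18350, 5349). For queen against worker (8148 calls, highest other 8488) 2 of the 35 splits gave as many calls, so chance cannot be excluded. The other one, queen 1, 3 and 4 with worker 3 against the rest, put the 3 libraries with the lowest share of counts in the strongest decile of peaks on one side. For calls shared by gynes and queens against workers, 1 of 100 groupings of the 12 female libraries, the real one, reached 4389. The highest other, 4352, kept the 4 workers together and mixed gynes with queens.

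The number of gene lists passing camera with the preset correlation could arise by chance in 5 of the 6 comparisons. Lists, splits of 35 reaching them (real one included) and highest other were 6, 5 and 7 for gyne against worker. They were 5, 7 and 8 for queen against gyne and 5, 5 and 6 for male against gyne. They were 5, 7 and 5 for male against queen, 3, 11 and 4 for male against worker and 13, 1 and 11 for queen against worker. The last margin was lost without worker replicate 4 (10 lists), so chance stays open there too. Taken singly, 32 of the 37 lists called, but also 82 of the 143 not called, had a larger absolute mean log2 difference between the castes than in any other of the 35 splits, and the lists called had been selected for such a difference. For the relation of RNA with promoter accessibility chance could not be excluded: with fold changes taken as differences of mean log CPM, absolute rho was 0.0561 (reached by 16 of 35 splits, highest other 0.156) for gyne against worker, 0.0842 (reached by 12 of 35 splits, highest other 0.126) for queen against gyne, 0.0316 (reached by 28 of 35 splits, highest other 0.169) for queen against worker, 0.0552 (reached by 10 of 35 splits, highest other 0.0694) for male against gyne, 0.0754 (reached by 13 of 35 splits, highest other 0.107) for male against queen and 0.0762 (reached by 7 of 35 splits, highest other 0.103) for male against worker.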
